A study of Homo sapiens with 9 samples.

How the data were processed

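RNA of SK-N-AS cells, a human neuroblastoma line, was measured on 9 Affymetrix expression arrays. Per the labels, the cells received the RE-EX1 construct, which carries full-length NRSF, or the HZ4 construct, which carries a truncated NRSF, or were untreated, and each of these 3 series has an array at 0, 24 and 48 h. Biotin-labelled cRNA was made from total RNA extracted with Trizol, per the labels' protocols. Each of the 9 groups holds 1 array. The description of the series speaks of triplicate samples per batch over several batches, but the labels give no batch or replicate number, and whether cultures were pooled onto an array is not stated.

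The deposited values are linear signal intensities, 1 per probe set and array, made with GCOS, per the submitters' processing notes; its version and algorithm settings are not given in the sources used here. There were 54675 probe sets, of which 62 are controls. After removal of the lowest and highest 2% of values, the mean signal was 150.02 on every array, so the authors had scaled all arrays to 1 target, and this scaling was kept.

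A floor was set at the 25th percentile of all values (signal 8.266) and the log2 was taken. Probe sets were joined to gene symbols through an annotation table, by Entrez ID for 41043 of them: 41097 named 1 gene and were used, 1801 named several genes and 11777 were not in that annotation, and both of these kinds were left out, as were the controls. The probe set with the highest mean over the 9 arrays stood for each of 19775 genes. Genes were kept when their mean log2 signal was above 4.2, the 40th percentile of all probe sets, which left 13804 genes. Of these, 900 are read by a probe set whose identifier marks possible cross-hybridization. Their values are uncertain, and they are called uncertain where named.

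With 1 array per group, the change of each series from its own 0 h array, the same change net of the untreated series, and the difference between both constructs have no replicate check. They are given as log2 differences and as counts of genes at 2-fold or more, without p-values, beside the same counts between the 3 pairs of 0 h arrays. The median of a gene list in such a difference was ranked among 10000 random lists of equal size, matched on mean signal in 20 bins (seed 1), as a description of these arrays.

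Tests used limma 3.58.1 in R 4.3.3 with the data.table package (1.17.8), as lmFit and eBayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted p under 0.05. The time model held series and time, so its 4 residual degrees of freedom are differences between the 3 series in their time course. The exposure model added a term for each construct at 24 and 48 h, and so compared the change of a construct series with that of the untreated series. It takes 24 and 48 h as repeated readings of 1 effect, and its 2 residual degrees of freedom are changes of that effect between 24 and 48 h, not replicate cultures. The p-values measure only the spread between these arrays. Each gene's variance is drawn toward a trend over all genes, which gives 16.5 total degrees of freedom for time and 16.3 for exposure. The exposure model fits every 0 h array exactly, so the spread of 0 h arrays does not enter its residuals. The number of arrays limits the precision of every value.

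There were 22 gene lists: RE1 neuronal target genes, NRSF and its corepressors, sympathoadrenal and mesenchymal neuroblastoma markers, neuronal cytoskeleton and axon genes, type I interferon response, NF-kB and cytokine genes, heat shock response, unfolded protein and integrated stress response, p53 target genes, G2/M and mitosis genes, DNA replication and S phase genes, immediate early genes, cholesterol synthesis, hypoxia and glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, TGF-beta and matrix genes, and markers of epithelial, blood, Schwann and melanocyte, and endothelial cells. They were tested with limma's camera, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 22 lists of each contrast. The run with an estimated correlation rests on the model's residual degrees of freedom, 4 for time and 2 for exposure. It therefore has little power, least for exposure. Calls of list members are given over all genes and "adjusted over the list alone".

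The comparisons, tests, lists, settings and the rule for named genes were fixed before the data were examined. The rule takes REST; per series, the 10 genes up and 10 down with the largest smaller change of 24 and 48 h, where both are of 1 sign and at least 2-fold; the same net of untreated and between constructs; up to 10 calls of each exposure contrast; the 10 time calls in each direction with the largest change at 48 h; and the 4 members of each list with the largest absolute change. Genes named outside it were chosen after their values were seen.

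The tests were run on simulated data before they were run on the real values, in 5 simulations per contrast with 200 genes changed. The simulated signals took each probe set's mean from the real arrays and its noise from an exposure model fitted to them. That noise leaves out the spread of 0 h arrays, so the shares below are no independent check. For 24 h over 0 h (13884 genes), 48.4% of genes changed 2-fold and 65.2% of those changed 4-fold were recovered, with 6% false calls. For the full-length exposure (13868 genes) these shares were 0%, 18.2% and 4.2%, and for the truncated exposure (13874 genes) 0%, 14.6% and 1.4%. A list shifted by 0.5 log2 was called in 4 of 5 simulations for 24 h and in 5 of 5 for each exposure. The simulated noise was independent between genes, so these runs do not check the list tests where genes are correlated. In the real data the estimated correlation reached 0.43, for ribosomal protein genes over time.

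Alternatives to these settings covered quantile normalization, median centring, other floors, other filters, the mean of a gene's probe sets, a 1.5-fold threshold, other variance priors, models without the series term and fits without single arrays or series. Added after seeing the data were cyclic loess scaling, covariates for the ACTB 3'/5' ratio and the 18S control signal, time fits and list tests without the truncated 24 h array, list tests without the series term, medians of 2 lists with a 0 h array replaced by the truncated one, and the contrast of 48 h over 24 h.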

Results

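Signals of 13804 genes were compared across 9 arrays of SK-N-AS cells, from 3 series (full-length NRSF, truncated NRSF and untreated) at 0, 24 and 48 h, with 1 array in each group. NRSF, the product of REST, is a repressor that silences neuronal genes through RE1 elements. The median signal of an array lay between 30.87 and 42.67, and 21.9% to 26.9% of an array's values were at or below the floor. Across genes, each array had a median correlation of 0.922 to 0.931 with the other arrays, except the truncated 24 h array at 0.909. On that array the dimmest 20% of genes read a median of 0.52 log2 above their mean over arrays and the brightest 20% read −0.12, against −0.06 to 0.32 and −0.04 to 0.10 on the others (genes are not independent replicates). The ratio of the 3' to the 5' ACTB control probe sets was 2.251 to 4.187.

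REST signal (chromosome 4, 56907900 to 56935844, GRCh38.p14) was read first, since both constructs are built on this gene. On its brightest probe set signals at 0, 24 and 48 h were 171.1, 268.3 and 273.5 in the full-length series. They were 162, 323.1 and 341.6 in the truncated series, and 177.2, 444.7 and 260.3 in the untreated series. REST was thus no higher on the construct arrays than on the untreated array at 24 h, and at 48 h it was higher on both. The other 2 probe sets were dim, with signals of 3.946 to 122, and differed in the direction of their changes. Whether any of these probe sets lies within the coding sequence that a construct carries is not given in the sources used here, so REST signal does not check the constructs.

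The series description compares each time point with its own 0 h array. IL24, a cytokine of the IL10 family, was higher in each series, by 4 and 4.40 log2 at 24 and 48 h with full-length NRSF, 4.39 and 4.73 with truncated NRSF, and 4.47 and 5.04 in untreated cells. In the full-length series DLX2, a homeobox gene of forebrain neurons, was higher by 5.58 and 3.81, and ISG20, an interferon-induced exonuclease, by 3.50 and 3.26. HMOX1, which encodes heme oxygenase, was higher by 3.35 and 3.48 with truncated NRSF and by 2.65 and 3.25 in untreated cells. SDC3, a heparan sulfate proteoglycan of neurons, differed by −4.39 and −3.39 with truncated NRSF but by 1.17 and 0.43 with full-length NRSF. In untreated cells the chemokine receptor gene CXCR4 was higher by 3.08 and 3.06, and RAB3A, a GTPase of synaptic vesicles and an RE1 target, differed by −3.10 and −2.97. DLX2, ISG20, CXCR4, SDC3 and RAB3A had 1 array of these pairs at the floor, so the value that uses it is a lower bound of the difference.

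At 2-fold or more, 1336 genes were higher and 1374 lower at 24 h with full-length NRSF (19.6% of genes), and 1105 and 1456 at 48 h (18.6%). With truncated NRSF these counts were 2107 and 1630 at 24 h (27.1%) and 1335 and 1306 at 48 h (19.1%). In untreated cells they were 1216 and 1355 at 24 h (18.6%) and 1167 and 1283 at 48 h (17.7%). Between pairs of 0 h arrays, 2055, 2055 and 1818 genes differed by as much (14.9%, 14.9% and 13.2%). Under quantile normalization the truncated 24 h split turned to 1701 higher and 2015 lower. All 3 series were 2-fold higher at 24 h for 265 genes and lower for 129, where independent lists of these sizes would share 18 and 16. At 48 h these numbers were 116 and 118, against 9 and 13. The expected numbers take every gene as equally likely to pass 2-fold, but dim genes passed more often, so they are too low. With the filter at the 60th percentile 10444 genes were left, and 1208 instead of 2710 passed 2-fold at 24 h with full-length NRSF. All 6 changes were 2-fold or more for 53 genes higher and 20 lower.

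Gene groups that moved alike in all 3 series were the question of the time model, which tests 24 h over 0 h across series (n = 3 arrays per time). IL24 rose by 4.29 ± 0.15 log2 (standard error; adjusted p = 3.6e-11), DLX2 by 4.02 ± 0.42 (8.2e-06), CXCL8, a neutrophil chemokine read by an uncertain probe set, by 3.88 ± 0.20 (4.3e-09), and HMOX1 by 2.88 ± 0.21 (1.5e-07). C11orf96 rose by 3.28 ± 0.21 and the cytokine gene IL11 by 2.50 ± 0.18. HMG20B, a subunit of the LSD1 and CoREST complex that NRSF recruits, fell by 2.03 ± 0.30 (adjusted p = 0.00023), and SOX11, a transcription factor of sympathetic neuroblasts, fell by 1.31 ± 0.16 (5.4e-05). The matrix genes ADAMTS2 and SVEP1 fell by 2.06 ± 0.67 (adjusted p = 0.047) and 1.94 ± 0.51 (0.016). All 10 of these changes had the same sign in 3 of 3 series. ADAMTS2 kept its call in 3 of 16 alternatives and SVEP1 in 9 of 16, and with the mean of all probe sets they stood at −0.41 (adjusted p = 0.72) and −0.52 (0.52), and DLX2 at 2.51.

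Immediate early genes, the fast transcriptional targets of growth and stress signals, were the group with the largest shift at 24 h: 17 of 22 members rose and 0 fell, with a median change of 1.88 log2 (camera adjusted p = 2.3e-19; adjusted p = 0.028 with an estimated correlation). ATF3 rose by 3.36 ± 0.36, NR4A3 by 2.87 ± 0.53, EGR3 by 2.81 ± 0.52 and KLF4 by 2.77 ± 0.17. The median was 1.44, 1.71 and 1.77 in the full-length, truncated and untreated series, each at percentile 100 of random lists. Genes of the unfolded protein and integrated stress response followed, with 16 of 30 up and 2 down and a median of 0.78 (adjusted p = 1.4e-08; adjusted p = 0.028 with an estimated correlation). Among them were ATF3, which both lists hold, the cystine transporter gene SLC7A11 at 1.98 ± 0.20 and DDIT3, a mediator of stress-induced cell death, at 1.95 ± 0.17. Of 21 NF-kB and cytokine genes 8 rose and 1 fell, with a median of 0.77 (adjusted p = 3e-04; adjusted p = 0.27 with an estimated correlation), among them the chemokine gene CCL20 at 3.16 ± 0.54 and LIF at 2.16 ± 0.23. Of 21 p53 target genes 9 rose and 1 fell, with a median of 0.33 (adjusted p = 0.003; adjusted p = 0.12 with an estimated correlation). AEN rose by 2.37 ± 0.35, TP53INP1 by 2.34 ± 0.59, the cell cycle inhibitor gene CDKN1A by 2.18 ± 0.22 and PLK3 by 2.16 ± 0.41. Adjusted over the list alone, calls up and down numbered 20 and 1 for immediate early genes, 19 and 3 for the stress response, 9 and 1 for NF-kB genes and 9 and 2 for p53 targets. The p53 call ended with the mean of all probe sets (median 0.09, adjusted p = 0.23) with that of PLK3 (0.33, 0.71). Under that setting the NF-kB median was 0.35, ATF3 stood at 1.97 and NR4A3 at 1.88. With the filter at the 60th percentile the NF-kB median was 0.33, and without the full-length series TP53INP1 lost its call at 1.32 (adjusted p = 0.20).

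Genes of cell division were lower at 24 h. Of 30 G2/M and mitosis genes 19 fell and 0 rose, with a median of −0.67 (adjusted p = 1.3e-13; adjusted p = 0.028 with an estimated correlation), and 28 or 29 of the 30 were lower in each series. The mitotic kinesin genes KIF20A and KIF23 fell by 1.53 ± 0.21 and 1.06 ± 0.28, MKI67, which encodes the proliferation marker Ki-67, by 1.14 ± 0.17, and the spindle gene ASPM by 1.02 ± 0.15. Of 29 DNA replication and S phase genes 13 fell and 0 rose, with a median of −0.55 (adjusted p = 1.2e-07; adjusted p = 0.12 with an estimated correlation). The flap endonuclease gene FEN1 fell by 1.06 ± 0.24, UHRF1 by 0.99 ± 0.18 and the replicative helicase subunit gene MCM3 by 0.93 ± 0.16. Of 26 mesenchymal neuroblastoma markers 9 fell and 3 rose, with a median of −0.28 (adjusted p = 0.015; adjusted p = 0.25 with an estimated correlation). The matrix genes TGFBI, FN1 (uncertain probe set) and COL3A1 fell by 1.89 ± 0.17, 1.43 ± 0.16 and 1.30 ± 0.15, while FOSL1, an AP-1 subunit, rose by 1.56 ± 0.20. Of 22 oxidative phosphorylation genes 3 fell, UQCRC2 by 0.73 ± 0.13, UQCRQ by 0.72 ± 0.17 and COX8A by 0.53 ± 0.13, with a median of −0.20 (adjusted p = 0.0079; adjusted p = 0.59 with an estimated correlation). Without the truncated 24 h array this median was −0.14 (adjusted p = 0.11), KIF23 stood at −0.61 (0.13) and FEN1 at −0.67 (0.062). Without the truncated series KIF23 stood at −0.63 (0.14), FEN1 at −0.50 (0.085) and UQCRQ at −0.41 (0.14). All of these calls ended. With the mean of all probe sets the mesenchymal call ended (median −0.07, adjusted p = 0.51), and FN1 and UQCRC2 stood at −0.85 and −0.46. Adjusted over the list alone, calls down numbered 26 for mitosis, 19 for S phase, 9 for mesenchymal markers (4 up) and 3 for oxidative phosphorylation.

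Of NRSF and its corepressors, 7 of 26 fell and 2 rose at 24 h, with a median of −0.37 (adjusted p = 0.036; adjusted p = 0.25 with an estimated correlation), and 10 and 2 adjusted over the list alone. Besides HMG20B, the histone methyltransferase gene EHMT2 fell by 1.18 ± 0.22, while ZNF217 rose by 1.51 ± 0.15 and REST itself by 0.99 ± 0.21 (adjusted p = 0.0046), higher in 3 of 3 series. The calls of the list (median −0.17, adjusted p = 0.20), of EHMT2 (−0.20, 0.79) and of REST (0.72, 0.23) ended with the mean of all probe sets. That of REST also ended without the variance trend (adjusted p = 0.065) or the untreated series (0.82, 0.054), and that of the list with the filter at the 60th percentile (median −0.37, adjusted p = 0.083). Of 63 listed RE1 neuronal target genes, those with a known NRSF binding element, 38 were kept. The others were too dim for the filter or had no usable probe set, so silent targets were not tested. The 38 showed no shift as a group: 2 rose and 3 fell, and the median was 0.00 with a mean of 0.10 (camera adjusted p = 0.88). The same 2 and 3 were called adjusted over the list alone. INA, a neurofilament gene, rose by 1.82 ± 0.24, and CRH, a stress hormone gene, fell by 1.55 ± 0.23. The remaining calls, chosen after their values were seen, were the neuropeptide precursor gene VGF (uncertain probe set) at 1.17 ± 0.21, the granin gene SCG2 at −0.84 ± 0.16 and the potassium channel gene KCNH2 at −0.64 ± 0.19.

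Other lists were not called at 24 h, although single members were. Of 29 type I interferon response genes 5 rose and 2 fell, among them IFIT2 (2.63 ± 0.31), OASL (2.59 ± 0.26), RSAD2 (2.48 ± 0.40) and ISG20 (2.07 ± 0.51), and the median of −0.13 differed in sign from the mean of 0.29 and from the test (adjusted p = 0.40). Of 27 hypoxia and glycolysis genes 9 rose and 2 fell around a median of −0.03, against a mean of 0.17 and a test upward (adjusted p = 0.31), with the vasodilator peptide gene ADM at 1.89 ± 0.17. Of 26 TGF-beta and matrix genes 3 rose and 4 fell (median −0.10, adjusted p = 0.76), with the activin subunit gene INHBA at 2.45 ± 0.28 and the collagen gene COL6A3 at −1.67 ± 0.24. Of 19 sympathoadrenal markers the receptor tyrosine kinase gene RET (−1.96 ± 0.24) and DDC (−0.93 ± 0.20) fell and 1 rose (median −0.17, adjusted p = 0.40). Of 21 neuronal cytoskeleton and axon genes DPYSL3 (−1.40 ± 0.22) and 2 others fell and 1 rose (median −0.16, adjusted p = 0.40). Medians were −0.20 for 14 heat shock genes (1 up, 3 down; adjusted p = 0.27), −0.20 for 17 cholesterol synthesis genes (2 and 2; 0.65) and −0.16 for 25 cytosolic ribosomal protein genes (0 and 0; 0.088). Among markers of other cell types, 2 of 8 epithelial, 0 of 10 blood, 0 of 6 Schwann and melanocyte and 1 of 5 endothelial genes were called, all up, with medians of 0.18, −0.52, 0.28 and 0.19 and adjusted p of 0.40, 0.97, 0.40 and 0.39. The blood median differed in sign from its test, which pointed up with a mean of −0.02. With the mean of all probe sets DDC (−0.59, adjusted p = 0.28) and DPYSL3 (−0.71, 0.12) lost their calls and INHBA stood at 1.57, and without the full-length series ISG20 lost its call at 1.36 (0.078).

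**Figure D1:**
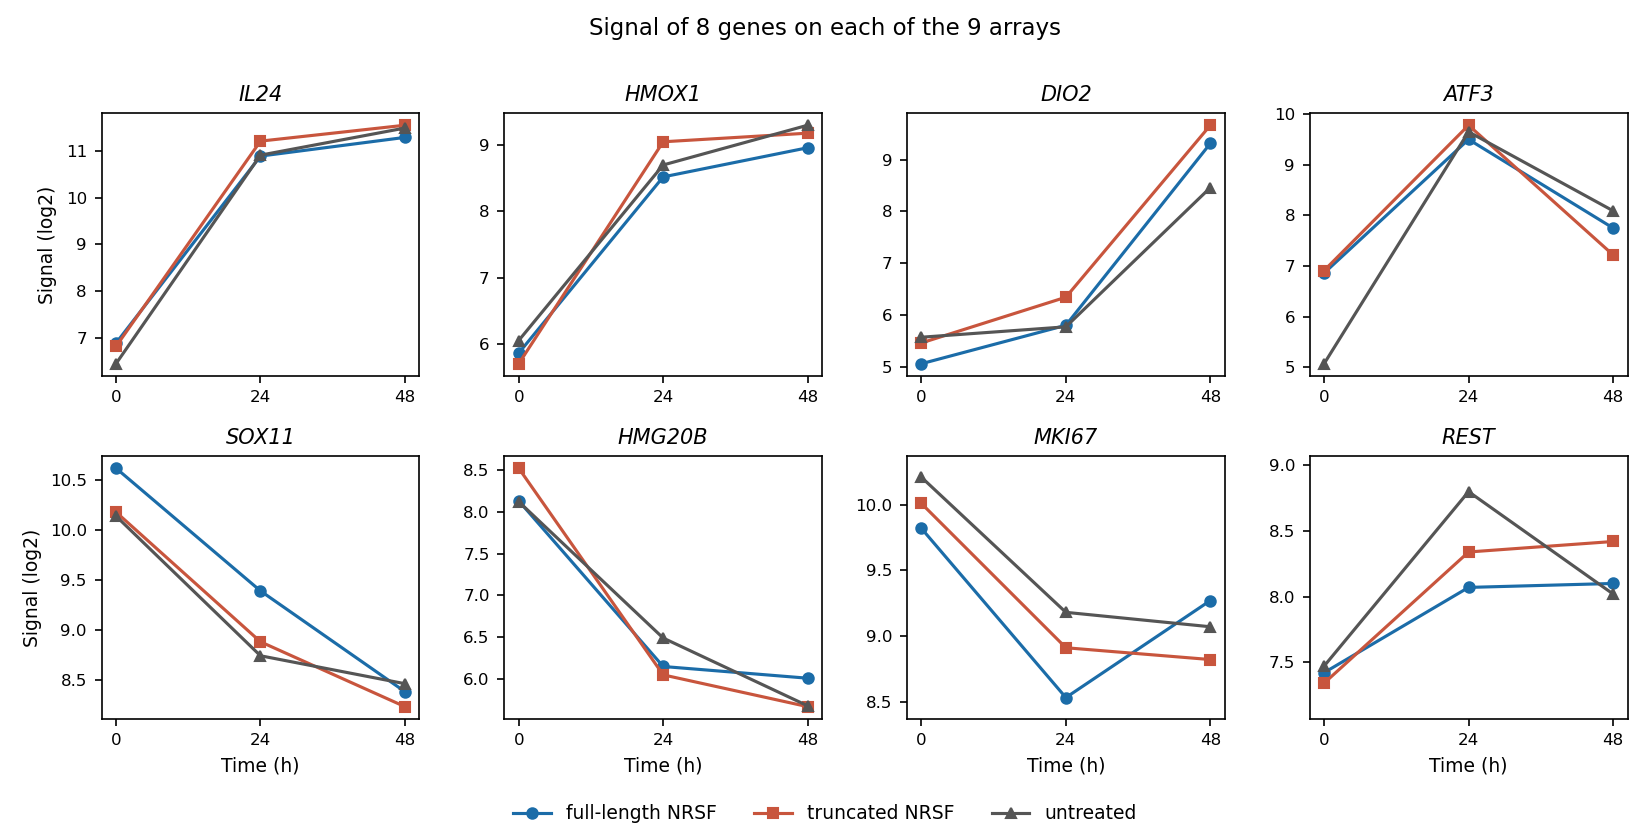
Each panel plots the log2 signal (vertical axis) of 1 gene against time in hours (horizontal axis), with 1 point per array and a line joining the 3 arrays of a series. IL24, HMOX1 and ATF3 were higher at 24 h in all 3 series, SOX11, HMG20B and MKI67 were lower, and DIO2 was highest at 48 h.

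**Figure D2:**
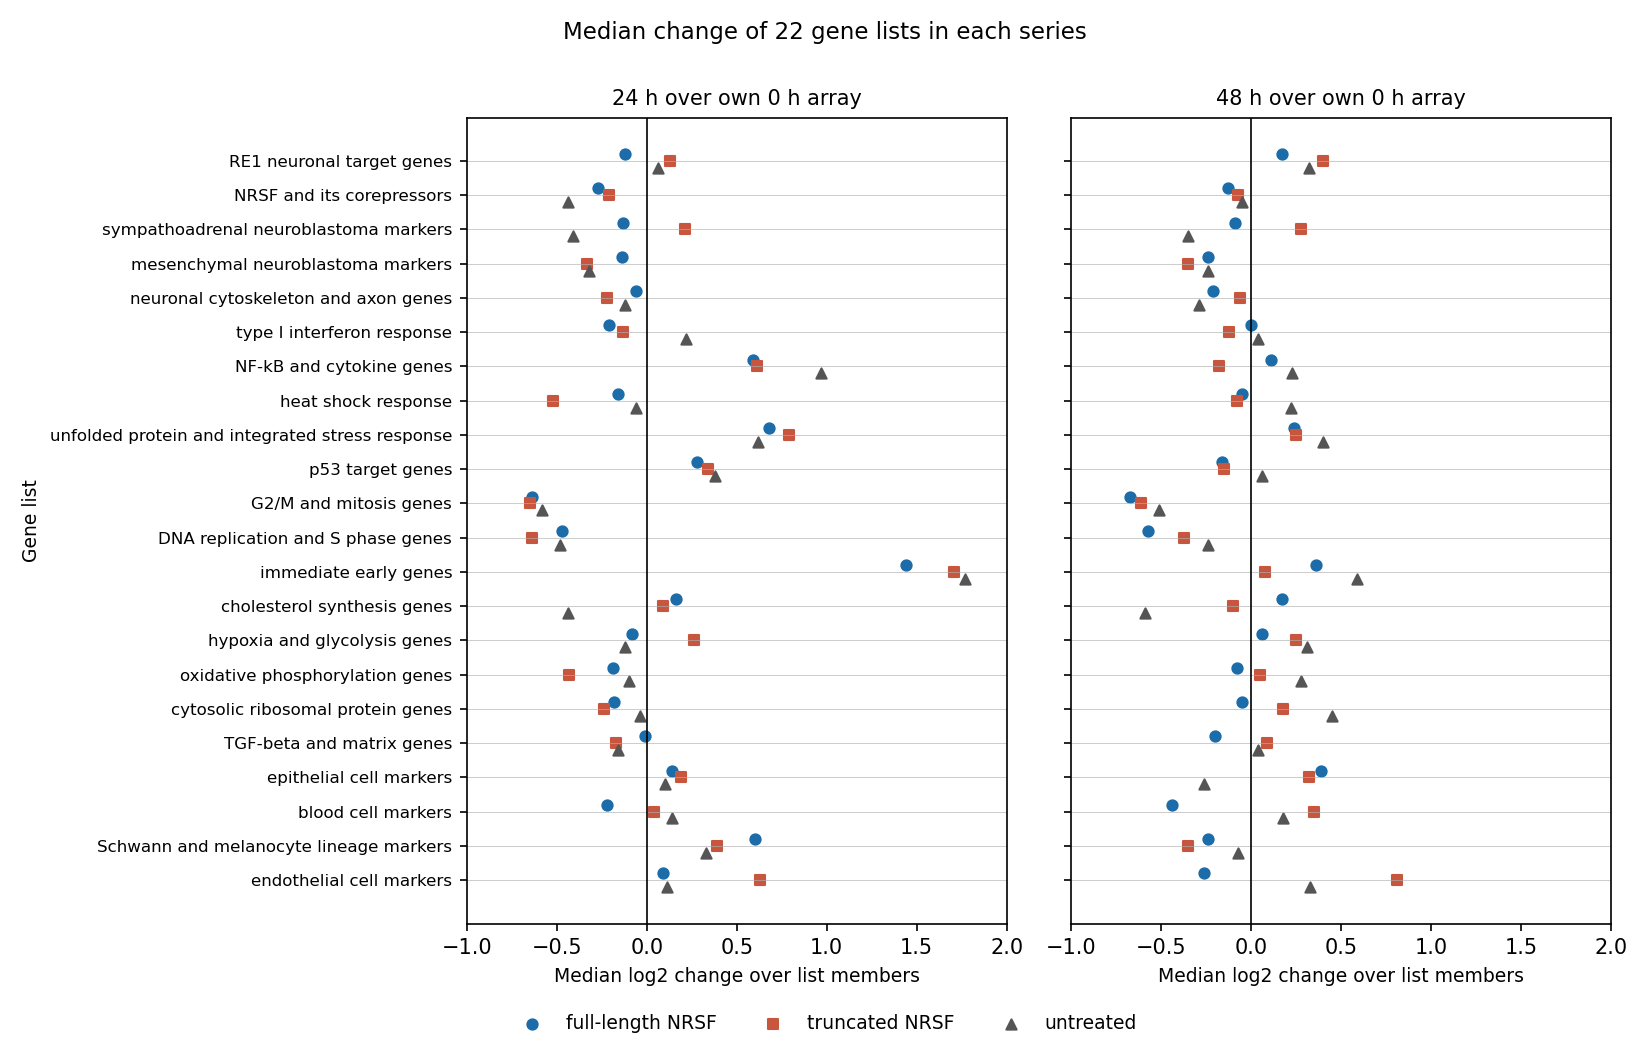
Points give the median log2 change of each of 22 gene lists (vertical axis) from the own 0 h array at 24 h and at 48 h (horizontal axes), with 1 point per series. Immediate early genes stood at 1.44, 1.71 and 1.77 at 24 h, and G2/M and mitosis genes lay below 0 in all 6 comparisons.

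In all, limma called 1110 genes up and 1132 down at 24 h (2242 of 13804; 3882 had an unadjusted p under 0.05, where 690 are expected by chance). The count was 539 without the variance trend, 1264 without the filter on low signals, 1213 with the mean of all probe sets of a gene and 1385 without the truncated 24 h array. Without the full-length, truncated or untreated series it was 890, 1377 and 1465. Of the 1465 genes called without the untreated series, 1363 (93%) had the same sign in the untreated arrays left out, against 65.2% of all genes.

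At 48 h the time model asked which changes stood later. IL24 and HMOX1 were up by 4.72 ± 0.15 (adjusted p = 7.6e-12) and 3.28 ± 0.21 (1.6e-07). DIO2, which encodes the enzyme that activates thyroid hormone, rose by 3.77 ± 0.31 (2.9e-06), and the protease gene PRSS35 by 3.13 ± 0.42. SOX11, HMG20B and RET fell by 1.96 ± 0.16 (adjusted p = 3.2e-06), 2.47 ± 0.30 and 1.66 ± 0.24, and the prostaglandin receptor gene PTGFR by 3.27 ± 0.69 (0.0083). All of these had the same sign in 3 of 3 series. REST stood at 0.77 ± 0.21 (adjusted p = 0.035). REST (0.40, adjusted p = 0.58) and PTGFR (−1.58, 0.12) lost their calls with the mean of all probe sets, and PTGFR stood at −1.82 with the floor at the 40th percentile. Over all alternatives REST kept its 48 h call in 10 of 17 and PTGFR in 12 of 16.

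G2/M and mitosis genes stayed low at 48 h, with 18 of 30 down and 0 up (23 down adjusted over the list alone) and a median of −0.60 (adjusted p = 2.7e-16; adjusted p = 0.037 with an estimated correlation). KIF23 fell by 1.21 ± 0.28, KIF20A by 1.13 ± 0.21, the cyclin gene CCNA2 by 0.99 ± 0.16 and MKI67 by 0.96 ± 0.17. S phase genes had 6 of 29 down, 13 adjusted over the list alone, E2F2 among them at −1.11 ± 0.24, and a median of −0.42 (adjusted p = 3e-06; adjusted p = 0.23 with an estimated correlation). Immediate early genes had 7 of 22 up and 3 down (8 and 3 adjusted over the list alone) and a median of 0.36 (adjusted p = 0.0014; adjusted p = 0.32 with an estimated correlation), with NR4A3 at 2.15 ± 0.53, NR4A2 at 2.11 ± 0.42 and the phosphatase gene DUSP1 at 2.09 ± 0.19. In the stress response 11 of 30 were up and 3 down (13 and 4 adjusted over the list alone), with a median of 0.33 (adjusted p = 0.0023; adjusted p = 0.23 with an estimated correlation): the amino acid transporter genes SLC7A11 and SLC7A5 stood at 1.48 ± 0.20 and 1.34 ± 0.18, and the endoplasmic reticulum chaperone gene PDIA4 at −1.41 ± 0.24. Mesenchymal markers had 7 of 26 down and 1 up (8 and 1 adjusted over the list alone; median −0.19, adjusted p = 0.021; adjusted p = 0.32 with an estimated correlation), with TGFBI at −1.44 ± 0.17 and SNAI2, a regulator of mesenchymal transition, at 0.96 ± 0.15. Hypoxia and glycolysis genes had 3 of 27 up, 7 adjusted over the list alone, with a median of 0.22 (adjusted p = 0.0064; adjusted p = 0.41 with an estimated correlation), among them ADM at 1.43 ± 0.17 and the angiogenic factor gene VEGFA at 0.77 ± 0.15. Ribosomal protein genes had a median of 0.20 with 0 of 25 called (adjusted p = 0.0051; adjusted p = 0.66 with an estimated correlation), which dropped to 0.02 with quantile normalization (adjusted p = 0.87). The RE1 target genes were not called as a list (median 0.28, adjusted p = 0.28): 3 of 38 rose, VIP by 1.07 ± 0.28 and, chosen after their values were seen, INA by 0.97 ± 0.24 and VGF by 0.77 ± 0.21. Corepressors had a median of −0.13 (adjusted p = 0.15). Of the other lists called at 24 h, p53 targets had a median of −0.16 (adjusted p = 0.63) and NF-kB genes of −0.11 (0.33), with means of 0.10 and 0.26 and tests upward, and oxidative phosphorylation genes of 0.08 (0.44). With the mean of all probe sets the calls of mesenchymal markers (median −0.06, adjusted p = 0.69), hypoxia genes (0.15, 0.079) and E2F2 (−0.62, 0.38) ended and PDIA4 stood at −0.89. The stress response median was 0.53 without the filter and 0.12 with the filter at the 60th percentile. Without the truncated series NR4A3 lost its call at 1.36 (adjusted p = 0.11), and VIP stood at 0.65 without the full-length series (0.34) and 1.65 without the untreated series.

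The 48 h calls numbered 621 up and 535 down (1156; 3133 unadjusted), or 831 and 450 after median centring. The count was 18 without the variance trend, 394 without the filter on low signals, 477 with the mean of all probe sets, and 212, 660 and 501 without the full-length, truncated or untreated series.

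The effect of full-length NRSF was read net of the change in untreated cells. The design text does not mention the untreated arrays, and whether they were run together with the construct arrays is not given in the sources used here, so every value net of untreated also holds any difference in handling between the series. Cholesterol synthesis genes were higher as a list, by a median of 0.66 log2 over 17 genes (camera adjusted p = 7.4e-07; adjusted p = 0.80 with an estimated correlation), although 0 members were called, over all genes or adjusted over the list alone. SREBF2, the transcription factor of the pathway, stood at 1.84 ± 0.91 (adjusted p = 1), and the enzyme genes DHCR7 at 1.55 ± 0.67 and EBP at 1.38 ± 0.47. The list's own median at 48 h was 0.17 with full-length NRSF and −0.59 in untreated cells, where 17 of 17 members were lower. Immediate early genes were lower as a list (median −0.60, adjusted p = 8.1e-05; adjusted p = 0.80 with an estimated correlation), with 2 of 22 down adjusted over the list alone and ATF3 at −2.04 ± 0.49 (adjusted p = 0.98). NF-kB and cytokine genes (−0.48, 0.0014; 2 of 21 down adjusted over the list alone, with IL6 at −2.34 ± 0.56), ribosomal protein genes (−0.31, 0.00039) and oxidative phosphorylation genes (−0.19, 0.018) were also lower, each with adjusted p = 0.80 with an estimated correlation. The last 2 calls ended with quantile normalization, at medians of −0.02 (adjusted p = 0.70) and −0.09 (0.23), and those of cholesterol synthesis and immediate early genes ended without the series term, at 0.08 (0.58) and −0.09 (0.19). The cholesterol median was 0.33 with the mean of all probe sets, and that of immediate early genes −0.37 with the floor at the 40th percentile.

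The RE1 target genes were not called with full-length NRSF net of untreated: their median of −0.25 differed in sign from their mean of 0.07 and from the test (adjusted p = 0.64), with 0 of 38 called over all genes or adjusted over the list alone. CHGB, a granin gene, stood at 3.20 ± 1.29 (adjusted p = 1). At 24 h and 48 h the net median was 0.22 and −0.22, at percentiles 87.94 and 22.74 of random lists. The list median was 0.19 with the mean of all probe sets and 0.04 with the filter at the 60th percentile or without the series term. Corepressors had a median of −0.03 (adjusted p = 0.86).

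By single genes, limma called 1 for full-length NRSF, MEF2D, a transcription factor of muscle and neurons, at −5.05 ± 0.72 (adjusted p = 0.034). MEF2D was lower in 2 of 2 readings, which share their 0 h arrays. In this contrast 578 genes had an unadjusted p under 0.05, where 690 are expected. The call rests on the untreated 0 h array, where MEF2D was at the floor (log2 3.05, against 6.24 to 7.55 on the other 8 arrays). Its size depends on the floor: MEF2D stood at −6.51 with no floor and at −3.61 (adjusted p = 1) with the floor at the 40th percentile. The value was −1.36 (adjusted p = 1) with the mean of all probe sets and −0.99 (0.80) without the series term, and 2 other MEF2D probe sets gave −0.36 and 1.33. Without the full-length 24 h array MEF2D stood at −4.93 and also lost its call. The call also ended without the full-length 48 h, untreated 24 h or untreated 48 h array. The count was 8 without the truncated 24 h array and 9 without the truncated 48 h array, in fits with a single residual degree of freedom. At 2-fold or more, 1449 genes were higher and 1458 lower net of untreated at 24 h, and 1460 and 1752 at 48 h. Besides MEF2D, genes with differences at both times included MELTF-AS1 (5.78 and 4.66; uncertain probe set), C10orf90 (4.34 and 4.80) and CIDEB (4.27 and 5.11) among those higher and NAT8L, the N-acetylaspartate synthase gene (−5.31 and −4.97), and the glutamate receptor gene GRM5 (−4.06 and −5.41) among those lower. Mean log2 signals were 5.06 for MELTF-AS1 and 4.27 to 4.58 for the other 4. Each of the 5 had full-length or untreated arrays at the floor, and a net value joins several single arrays of opposite sign. The size of these differences is therefore uncertain and gives no order.

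Truncated NRSF net of untreated gave 5 calls, all down. UQCRB and NDUFA1, subunits of respiratory complexes III and I, fell by 2.06 ± 0.28 (adjusted p = 0.025) and 2.26 ± 0.35 (0.033), SLPI, a secreted protease inhibitor gene, by 1.97 ± 0.31 (0.033), and CRABP2, a retinoic acid carrier gene, by 2.45 ± 0.39 (0.033). MIR1244-3, read by an uncertain probe set, fell by 1.95 ± 0.31 (0.033). Each was lower in 2 of 2 readings, but both readings subtract the same 0 h arrays and are not independent. On the truncated 0 h array each was 0.80 to 1.13 log2 above the other 0 h arrays. All 5 calls ended without the series term, with UQCRB at −1.51 (adjusted p = 0.15), NDUFA1 at −1.24 (0.19), SLPI at −0.68 (0.50), CRABP2 at −1.43 (0.15) and MIR1244-3 at −1.30 (0.14). They also ended with the mean of all probe sets, which moved UQCRB to −0.93 (adjusted p = 0.71) and left the other 4 values in place (0.49). Other probe sets of UQCRB gave −2.29, −0.59 and 1.20.

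**Figure D3:**
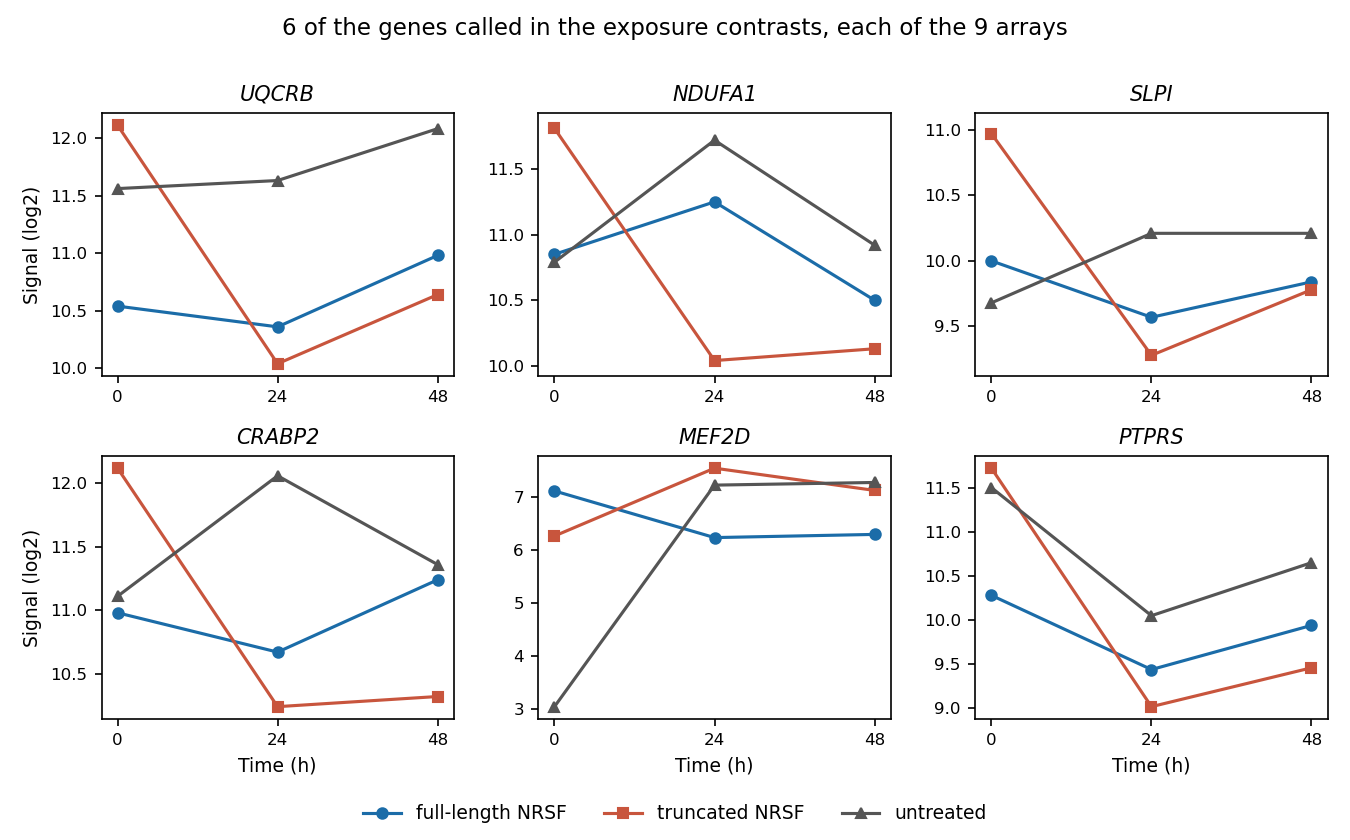
Each panel plots the log2 signal (vertical axis) of 1 gene against time in hours (horizontal axis), with 1 point per array and a line joining the 3 arrays of a series. UQCRB, NDUFA1, SLPI and CRABP2 were highest on the truncated 0 h array, and MEF2D was at the floor on the untreated 0 h array.

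Oxidative phosphorylation genes were lower as a list with truncated NRSF (median −0.18 over 22 genes, 2 called; 4 down adjusted over the list alone; adjusted p = 0.002; adjusted p = 0.81 with an estimated correlation). Immediate early genes (−0.35, 0.0084; 5 of 22 down adjusted over the list alone, ATF3 at −2.22 ± 0.49), NF-kB and cytokine genes (−0.60, 0.017; 4 of 21 down, IL6 at −1.99 ± 0.56) and interferon genes (−0.42, 0.041; 0 of 29) were lower too, and cholesterol synthesis genes were higher (0.42, 0.025; 0 of 17). Each of these had adjusted p = 0.81 with an estimated correlation, and the calls of immediate early, interferon and cholesterol genes ended without the series term, at −0.06 (adjusted p = 0.33), −0.12 (0.51) and −0.04 (0.91), the last with a change of sign. With the mean of all probe sets the calls of interferon (−0.03, adjusted p = 0.53), NF-kB (−0.34, 0.15) and cholesterol genes (0.09, 0.55) ended. The oxidative phosphorylation median was −0.08 with quantile normalization or without the series term. The RE1 target genes had a median of 0.40 and were not called (adjusted p = 0.56; 0 of 38 over all genes, 1 down adjusted over the list alone), with CHRNB2, a nicotinic receptor subunit gene, at −4.04 ± 1.40 (adjusted p = 0.43) and CHGA at −3.05 ± 1.09 (0.46). At 24 and 48 h the net median was 0.22 and 0.51, at percentiles 62.49 and 99.43 of random lists. The own median at 48 h was 0.40 with truncated NRSF, 0.17 with full-length NRSF and 0.32 in untreated cells (percentiles 99.15, 95.8 and 98.53). Corepressors had a median of 0.02 against a mean of −0.07 and a test downward (adjusted p = 0.66).

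The 5 calls for truncated NRSF came beside 1055 genes with an unadjusted p under 0.05, and their number depended on single arrays. It was 2 without the full-length 24 h or 48 h array, and all 5 calls ended without the untreated 24 h array. Without the truncated 24 h or 48 h array, the model fits the other of these 2 arrays exactly. The effect then rests on that single reading, so the number of calls is no check and is not given. At 2-fold or more, 2111 genes were higher and 1624 lower at 24 h net of untreated (1628 and 2078 with quantile normalization), and 1629 and 1591 at 48 h. Differences at both times included the growth factor gene GDF5 (6.15 and 4.61) and the calcium channel subunit gene CACNG2 (5.93 and 4.52), higher, and ENOX1 (−5.94 and −5.79) and the cholecystokinin receptor gene CCKBR (−4.10 and −4.17), lower, all dim, with mean log2 signals of 4.28 to 4.63. Each of these 4 had truncated or untreated arrays at the floor, so the size of the differences is uncertain.

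Full-length and truncated NRSF were compared by the difference of their effects. Its value no longer holds the untreated arrays, but its standard error and p-value still use them. UQCRB was higher with full-length NRSF by 1.90 ± 0.28 (limma adjusted p = 0.046) and PTPRS, a receptor phosphatase gene of neurons, by 1.88 ± 0.29 (0.046). These were the 2 calls (854 unadjusted), both higher in 2 of 2 readings, which share their 0 h arrays. Both calls ended without the series term, at 0.32 (adjusted p = 0.92) for UQCRB and 0.44 (0.86) for PTPRS, and with the mean of all probe sets, at 0.28 (0.98) and 0.12 (0.99). Other probe sets of UQCRB gave 1.73, 0.28 and −2.79, and the second brightest of PTPRS gave −0.70. None of the 22 lists differed between the constructs (camera; lowest adjusted p 0.26, or 0.99 with an estimated correlation). The RE1 target genes had a median difference of 0.06, against a mean of −0.15 and a test downward (adjusted p = 0.98; 0 of 38 called over all genes or adjusted over the list alone). By single differences, 3540 genes were 2-fold apart at 24 h and 3182 at 48 h. These included LGI1, an epilepsy gene of neuronal synapses (5.28 and 4.85), ADCYAP1R1, a neuropeptide receptor gene (4.50 and 4.01), and SLC6A2, the noradrenaline transporter gene (−5.19 and −4.74), with mean log2 signals of 4.34 to 5.50. ADCYAP1R1, and SLC6A2 at 24 h, had arrays at the floor, so the size of these values is uncertain. The count of calls was 0 with robust eBayes and without the untreated 24 h or untreated 48 h array, and 4 without the untreated 0 h array. Both calls also ended without the full-length 24 h or full-length 48 h array. Without a 24 or 48 h array of a construct, the difference rests on a single reading of that construct. Counts from such fits are no check and are not given.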

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

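The tests for technical explanations in this part were all chosen after the results were seen, and the contrasts between series were fixed before the data were examined.

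8 differences between series passed their test. Net of untreated cells, MEF2D stood at −5.05 ± 0.72 with full-length NRSF (adjusted p = 0.034, limma), a size set by the floor: −6.51 with no floor and −3.61 (adjusted p = 1) with the floor at the 40th percentile. With truncated NRSF, CRABP2 stood at −2.45 ± 0.39, NDUFA1 at −2.26 ± 0.35, UQCRB at −2.06 ± 0.28, SLPI at −1.97 ± 0.31 and MIR1244-3 (uncertain probe set) at −1.95 ± 0.31 (adjusted p = 0.025 for UQCRB and 0.033 for the others, limma). Between full-length and truncated NRSF, UQCRB differed by 1.90 ± 0.28 and PTPRS by 1.88 ± 0.29 (adjusted p = 0.046 for both, limma). This contrast uses the same truncated 0 h array, and without the series term the values were 0.32 (adjusted p = 0.92) and 0.44 (0.86), and with the mean of all probe sets 0.28 (0.98) and 0.12 (0.99). The 18S ribosomal RNA control probe set at the 5' end is not among the genes compared. It read 11287, 7855 and 451 on the full-length 0, 24 and 48 h arrays, against 2161 on the highest untreated array.

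At 24 h, immediate early and stress response genes were higher and mitosis genes lower, in all 3 series. RNA quality, read by the ACTB 3'/5' ratio, and ribosomal RNA, read by the 18S signal, were each added to the time model, and the highest adjusted p of the 3 lists was 2.1e-08 with either and 8.5e-09 after cyclic loess, which removes a trend of change with signal. These 3 corrections moved genes by a median of 0.017, 0.094 and 0.034 log2. The list medians of 1.88, 0.78 and −0.67 became 1.90, 0.77 and −0.68 with the ACTB ratio. They became 1.85, 0.79 and −0.71 with the 18S signal and 1.86, 0.81 and −0.65 after cyclic loess. A trend with signal is thus not the whole cause. From 0 to 24 h the ACTB ratio went from 4.187 to 3.629 (full-length), 2.251 to 3.227 (truncated) and 2.724 to 2.451 (untreated). With no shared direction, this covariate could barely move the time contrast, so it does not test RNA quality. The 18S signal went from 11287 to 7855 (full-length), 406 to 1485 (truncated) and 276 to 2161 (untreated). It shared no direction either, so its covariate is a weak test of ribosomal RNA, and no conclusion is drawn from it. With an estimated correlation the adjusted p was 0.028 before, and 0.073 and 0.07 with the covariates. Since untreated cells took part, a response to handling or culture time may underlie the pattern, as a hypothesis that has no separate test in this design.

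The 5 genes lower with truncated NRSF net of untreated had a median effect of −2.06. After cyclic loess, which evens out the compressed signals of the truncated 24 h array, it was −1.97 with a median standard error of 0.31 before and after, and 2 of 5 genes were still called (adjusted p 0.024 to 0.073). The calls ended there by small moves of p, since effect and error barely moved, and this argues against compressed signals as the whole cause. The 5 genes were also 0.80 to 1.13 above the other 0 h arrays on the truncated 0 h array. Without the series term the median was −1.30 with 0 of 5 called, so a high reading of that single array and an effect of the construct cannot be told apart, because the series has no other 0 h array.

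Cholesterol synthesis genes were higher and immediate early genes lower with full-length NRSF net of untreated, with 0 members called over all genes. Adjusted over the list alone, 2 immediate early genes were down with full-length NRSF and 5 with truncated NRSF. Both list calls ended with an estimated correlation (camera adjusted p = 0.80, and 0.81 for the same shifts with truncated NRSF). Against the mean of the other 0 h arrays, the cholesterol list stood at 0.56 on the untreated, −0.44 on the full-length and −0.12 on the truncated 0 h array, and immediate early genes at −0.27, 0.14 and 0.14. Without the series term, which removes all 3 baselines, the medians went from 0.66 to 0.08 and from −0.60 to −0.09, with a lowest adjusted p of 0.19. They were 0.20 and −0.22 with the untreated 0 h array replaced by the truncated one, and 0.40 and −0.42 with the full-length 0 h array so replaced. The untreated 0 h array is therefore a candidate explanation for part of the shift, while the full-length 0 h array, which had the highest ACTB 3'/5' ratio (4.187) and 18S signal, and an effect of NRSF stay open.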

How the results depend on the processing

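Cyclic loess, the covariates, list tests without the series term and fits without the truncated 24 h array were chosen after seeing the data; the other alternatives were fixed before. The time model already blocks the 3 times by series, and without this block it gave 2038 calls at 24 h and 967 at 48 h. Between series no paired analysis was possible because each group holds 1 array and the labels give no replicate number. None of the named gene results and none of the called list tests turned direction. The median of a list changed sign in 9 of 407 comparisons, of which 1 was of a called list, cholesterol synthesis with truncated NRSF, from 0.42 to −0.04 without the series term. The others were of RE1 targets and corepressors, which were not called there. Under quantile normalization the truncated 24 h split turned from 2107 higher and 1630 lower to 1701 and 2015, and net of untreated from 2111 and 1624 to 1628 and 2078. Of 168 compared counts, 82 stayed within 1.5 times the reported count and 86 moved further. Of 1734 comparisons of named genes 1468 kept direction and side of the threshold and 266 lost the call. Of 407 comparisons of list shifts 361 stayed on their side of the threshold and 46 lost the call. Of 94 gene results of the time model 38 were called under every alternative and 56 lost the call in at least 1, and of 8 in the exposure contrasts 0 were called under every alternative. IL24 stood at 4.16 to 4.43 at 24 h and 4.56 to 4.88 at 48 h over all alternatives. Of 102 gene results, 59 lost the call without the variance trend, 38 without the filter and 5 with quantile normalization, and 30 of 101 did with the mean of probe sets. That mean also takes in probe sets below the filter, such as those of PTPRS at mean log2 3.33 and 3.17, which can dilute a change. Of other probe sets above the filter, 77.6% had the sign of the called gene at 24 h and 79.8% at 48 h. In the exposure contrasts 1 of 2 (full-length), 2 of 3 (truncated) and 2 of 4 (their difference) did. Signal near background limits the differences of dim genes: 2.75% to 3.89% of an array's values of kept genes lay at the floor, and 21.9% to 26.9% over all probe sets. Except where named, the cause of a change below was not tested.

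Without the filter, 19775 genes were tested instead of 13804, and with the filter at the 60th percentile 10444, so counts of 2-fold genes rose and fell with the number of dim genes. From the own 0 h array at 24 and 48 h they were 4982 and 4880 (full-length), 6289 and 4693 (truncated) and 4491 and 4702 (untreated) without the filter, and 1208 and 994, 1925 and 1146, and 1119 and 889 with the stricter filter. Net of untreated they were 5808 and 6236 (full-length) and 6829 and 6162 (truncated) without it, and 1048 and 1186, and 1692 and 1297, with the stricter filter. At 1.5-fold, a lower threshold by construction, they were 5466 and 5234, 6817 and 5325, and 5323 and 5005 from the own 0 h array, and 5224 and 5522, and 6405 and 5654, net of untreated. With the floor at the 40th percentile, which flattens dim genes, untreated counts were 1678 and 1565.

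limma calls at 24 h numbered 1264 without the filter, 1213 with the mean of probe sets and 539 without the variance trend, and at 48 h 394, 477 and 18. Calls for full-length NRSF, truncated NRSF and their difference numbered 0, 0 and 0 under each of these 3 settings. With quantile normalization truncated NRSF gave 3 calls and the difference 4, after cyclic loess 2 and 4, with no floor 1 and 0, and with the filter at the 60th percentile 1 and 0. The floor at the 40th percentile gave 0, 1 and 0 for the 3 contrasts, and the model without the series term 0, 1 and 0. Robust eBayes gave 0 for the difference. Leave-one-out counts, which have fewer arrays, ran from 890 to 1465 at 24 h and from 212 to 1362 at 48 h, and from 0 to 9, 0 to 174 and 0 to 76 for full-length, truncated and their difference.

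List calls that ended are given as medians with adjusted p. With quantile normalization these were ribosomal protein genes at 48 h, 0.02 (0.87), and with full-length NRSF, −0.02 (0.70), and oxidative phosphorylation genes with full-length NRSF, −0.09 (0.23). After cyclic loess the same 3 were 0.02 (0.60), −0.10 (0.098) and −0.11 (0.11). The interferon list with truncated NRSF stood at −0.41 with the floor at the 40th percentile (0.052) and at −0.41 with the filter at the 60th percentile (0.11), where corepressors at 24 h stood at −0.37 (0.083). Without the filter, cholesterol synthesis with truncated NRSF was 0.35 (0.074). With the mean of probe sets, corepressors were −0.17 (0.20), mesenchymal markers −0.07 (0.51) and p53 targets 0.09 (0.23) at 24 h. Under that setting mesenchymal markers were −0.06 (0.69) and hypoxia genes 0.15 (0.079) at 48 h, and with truncated NRSF interferon genes were −0.03 (0.53), NF-kB genes −0.34 (0.15) and cholesterol genes 0.09 (0.55). Without the series term, immediate early and cholesterol genes were −0.09 (0.19) and 0.08 (0.58) with full-length NRSF, and interferon, immediate early and cholesterol genes −0.12 (0.51), −0.06 (0.33) and −0.04 (0.91) with truncated NRSF. Without the truncated 24 h array, oxidative phosphorylation genes at 24 h were −0.14 (0.11).

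With an estimated correlation medians do not move by construction, and 22 list calls ended. At 24 h these were corepressors (−0.37), mesenchymal markers (−0.28), NF-kB genes (0.77), p53 targets (0.33), S phase genes (−0.55) and oxidative phosphorylation (−0.20). At 48 h they were mesenchymal markers (−0.19), the stress response (0.33), S phase genes (−0.42), immediate early genes (0.36), hypoxia genes (0.22) and ribosomal protein genes (0.20). With full-length NRSF they were NF-kB (−0.48), immediate early (−0.60), cholesterol (0.66), oxidative phosphorylation (−0.19) and ribosomal protein genes (−0.31), and with truncated NRSF interferon (−0.42), NF-kB (−0.60), immediate early (−0.35), cholesterol (0.42) and oxidative phosphorylation genes (−0.18). Correlation alone did not end these calls, since this setting also rests on few residual degrees of freedom. For p53 targets at 24 h the estimate was 0.008, under the preset 0.01, yet the unadjusted camera p went from 0.00082 to 0.027. For interferon genes with truncated NRSF the estimate was −0.035, and the unadjusted camera p went from 0.0094 to 0.099.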

Other observations

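The contrast of 48 h over 24 h and the genes named for it were chosen after values were seen; the count over other splits of the arrays was planned. From 24 to 48 h across the 3 series (n = 3 arrays per time, limma), DIO2 rose by 3.16 ± 0.31 (adjusted p = 5.7e-05), PRSS35 by 3.32 ± 0.42 (0.00029), HPGD, which degrades prostaglandins, by 2.63 ± 0.33 (0.00025) and CRH by 1.63 ± 0.23 (0.00079). EGR1 fell by 2.77 ± 0.30 (0.00011), GADD45A by 1.52 ± 0.14 (4e-05), KLF6 by 1.35 ± 0.14 (7.9e-05) and TXNIP by 1.53 ± 0.17 (0.00014). In all, 237 genes rose and 246 fell (2469 unadjusted). Immediate early genes had a median of −0.94 with 11 down (camera adjusted p = 1.5e-21; adjusted p = 0.054 with an estimated correlation), and the stress response −0.33 with 5 down (adjusted p = 2.1e-06; adjusted p = 0.076 with an estimated correlation). NF-kB genes (−0.52, 2e-04; 0.38) and p53 targets (−0.42, 0.00044; 0.13) were also lower, and ribosomal protein (0.35, 3.8e-08; 0.38), oxidative phosphorylation (0.27, 2.1e-06; 0.38) and heat shock genes (0.34, 0.0051; 0.16) higher, given as median, adjusted p and adjusted p with an estimated correlation. G2/M and mitosis genes had a median of 0.04 (adjusted p = 0.64).

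The time model was also run on the other splits of the 6 arrays of each contrast. The series term stayed in the model, but time labels were moved without regard to series. At 24 h 1 of 10 splits, the real one, gave 2242 calls or more, and the highest of the others gave 0. At 48 h 1 of 10 gave 1156 or more, and the highest other gave 0. The splits are too few for a share under 0.05. Each other split mixes arrays of both times, so a real time effect counts as spread there, and their low counts are no added support.

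The effects of full-length and truncated NRSF net of untreated correlated across genes (Pearson r = 0.47). Both use the same untreated arrays, and simulated arrays with no effect gave r = 0.50 over 20 simulations.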
